A study of Mus musculus with 2 samples.

How the data were processed

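DNase-seq maps open chromatin by sequencing the sites at which the nuclease DNase I cuts nuclear DNA. The series held 2 libraries from spleen of female B6CASTF1/J mice, the first-generation hybrid of a C57BL/6 and a CAST parent, aged 36 days. The labels call them biological replicates 1 and 2, give them 2 biosamples and describe 2 differently numbered females, but attach 1 and the same donor entry to both. Separate animals are thus stated by the descriptions alone, and the spread between the libraries may in part be technical. The libraries form 1 group, so no comparison between groups exists. They were compared with each other, with chance placements and with random gene lists.

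Per the readme deposited with each library, peaks and the cut rate track were derived from the alignments of that library, and footprints from those alignments and the cut rate track, on the mouse assembly mm10 and without pooling of replicates. The aligner, the peak caller and the footprint caller are not given in the sources used here. The deposited peak lists carry a signal value per peak, which is the authors' own. In each library 100% of the signal values below 500 steps lay within 0.01 step of a whole multiple of 1 fixed step, which was 0.0106 in replicate 1 and 0.00513 in replicate 2, a ratio of 2.06. If a step is what 1 count is worth after scaling to depth, replicate 2 was the deeper library by that ratio. The scale and the total depth are not given in the sources used here, and signal served to describe and rank peaks within a library, to compare those rankings over shared peaks and, in 1 alternative, to set a stricter threshold.

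The deposited cut rate track gives a false discovery rate (FDR, a q-value) per run of bases and lists only runs under 0.05. Each library had 2 deposited peak lists. In the shorter list every peak, 42454 in replicate 1 and 60683 in replicate 2, held a run with an FDR of at most 0.001. In the longer list every peak, 61285 and 89476, held one of at most 0.05, which any listed run meets. Of these peaks 43803 and 62854 held a run of at most 0.001, slightly more than the shorter lists contain. The lists thus differed in stringency, whereas the plan had assumed a narrow and a broad list. The shorter list was used throughout, and the longer list took the place of the broad one among the alternatives. The peak position column of the deposited lists held 1 constant value, so midpoints were used in place of summits. The deposited footprints are short stretches protected from cutting inside open chromatin, and carry an FDR (q-value) threshold of 0.01 on every line and no strength of their own.

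Coordinates are those of the deposited lists on mm10, counted from 1. Sequence was taken from the matching reference assembly and genes from the basic GENCODE annotation, and 0 peaks or footprints reached past a chromosome end. A promoter was 1 kb to either side of an annotated start site. A peak was counted at a promoter if it overlapped the promoter of any protein-coding gene, and otherwise by its midpoint as exonic, intronic or intergenic. The locus of a gene was its body with 10 kb on either side. A peak was shared if it overlapped a peak of the other library by at least 1 base, and the chance level came from 100 circular shifts of a list along each chromosome. A footprint was shared if the overlap covered at least 50% of the shorter footprint. Its chance level came from 100 random placements of the footprints that lay wholly inside the overlap of shared peaks.

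Before the data were examined, lists of marker genes were fixed, 12 for cell types of the spleen, 9 for other tissues and 2 general ones. Of their 271 genes 270 were found in the annotation, and 1 erythroid gene was not analysed here. The share of a list with a promoter peak was placed among 10000 random lists of the same size, drawn from 21668 protein-coding genes and matched in 10 bins on promoter CpG content, observed over expected within 500 bases of the start sites. The median number of peaks per 10 kb of locus was placed among 10000 lists matched on gene length. Ties were split evenly. These percentiles describe the libraries and are no test across animals. The genes named were also fixed by rule. In each spleen list these were the 3 genes with the best mean rank of their strongest locus peak and up to 3 genes without a promoter peak in either library, in alphabetical order. In lists of other tissues they were up to 3 genes with a promoter peak in both libraries. To these came 13 landmark genes and the genes nearest to the 10 strongest peaks. Named outside this rule are 2 globin genes, the genes of the Y chromosome test, which were fixed with that test, and the genes in windows of 100 kb, which were chosen after their values were seen. Values of 2 genes that the rule selects are not reported here.

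Consensus sequences of 23 factors or factor families, likewise fixed, were searched on both strands in footprints widened by 5 bases on each side and in the central 100 bases of peaks. The control was the same consensus read backwards without complement. It keeps base composition but not CpG content: the backward CTCF, E2A, octamer and REST patterns hold a CpG that the forward ones lack, which makes them rare. The backward NRF1 and YY1 patterns hold more CpGs than the forward ones, so their ratios may be raised in the same way. The ETS pattern is the opposite case, with a CpG in the forward pattern alone, so that its ratio also moves with the CpG content of the regions. At variable positions of a consensus a CpG can also form unequally. It can form more often in the backward NFY, C/EBP and NF-kB patterns and in the forward EBF and IRF patterns. Their ratios are therefore not fully balanced for CpG content. The GC box of the SP/KLF family reads the same backwards and has no such control. Windows 1 kb away served as a second control, which differs from open chromatin in base composition.

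With 2 libraries of 1 group no test between groups exists, and values are given per library or as mean ± SD. Shares of a single library carry 95% Wilson intervals and motif ratios 95% exact binomial intervals, which cover counting error only. Where a control count was 0, the ratio is a lower bound against a floor of 3 counts. The procedures were tested on simulated data. With 59.9% of 42454 peaks planted as shared, 60.4% were found. Of 200 unchanged lists of 20 genes, drawn from 21668, 3.5% reached the 95th percentile, against 100% of 50 lists in which up to 8 promoters had been opened. All 1000 windows planted with the CTCF consensus among 20000 were found. Footprints placed independently were shared at 13.3%, against a chance level of 13.0%, among 10000.

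Alternatives fixed beforehand were promoter windows of 500 and 2500 bases, flanks of 50 kb and none, reciprocal overlap of 50%, overlap of footprints by 1 base, footprints inside peaks or not widened, the longer list, peaks above the median signal of the smaller list, the strongest 21227 peaks of each library, autosomes only, peaks away from promoters, random lists without matching, windows 1 kb away as motif control, genes in place of length for chromosomes, and each replicate left out. Chosen after seeing the data were equal numbers of peaks, with replicate 2 limited to its strongest 42454, and each replicate left out for the numbers of peaks and footprints. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9. Overlap counts were checked against bedtools 2.31.1 on simulated data, and Y peaks were matched to other chromosomes with BLAST+ 2.17.0.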

Results

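Open chromatin was mapped by DNase-seq in spleen of female B6CASTF1/J mice aged 36 days, in 1 group of 2 biological replicates with 1 library each. Replicate 1 had 42454 peaks and replicate 2 had 60683, a mean of 51568 ± 12890 (SD, n = 2). Their median widths were 189 and 191 bases, and they covered 8.18 and 11.5 Mb. Replicate 1 had 133725 footprints and replicate 2 had 246700, or 190212 ± 79885 (SD, n = 2). The median peak signal was 132 steps in replicate 1 and 222 steps in replicate 2. Total read depth was unknown.

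Which cell types of the spleen had open promoters was asked with the marker gene lists. All 22 B cell genes had a promoter peak in both libraries. Of 23 T cell genes, 11 had one in replicate 1 and 19 in replicate 2, a share of 65.2% ± 24.6 (SD, n = 2). Of 16 erythroid genes, 10 and 14 had one, or 75.0% ± 17.7 (SD, n = 2). These 3 of the 12 spleen lists lay at or above the 95th percentile of CpG-matched random lists in both libraries. Their percentiles were 100 and 100 for B cells, 99.4 and 100 for T cells, and 100 and 100 for erythroid cells. With the strongest 21227 peaks of each library, or with unmatched random lists, 1 list did so.

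Among B cell genes, Cd79a, which encodes a signalling chain of the B cell receptor, lies on chromosome 7 from 24897381 to 24902197 and had 8 peaks in its locus in replicate 1 and 12 in replicate 2. Its strongest locus peak, from 24904141 to 24904400, ranked 1061 of 42454 and 433 of 60683, but lay 6890 bases from its own start site, at the promoter of another gene. Pax5, the transcription factor that maintains B cell identity, had 16 and 25 locus peaks, the strongest of them exonic on chromosome 4 from 44704441 to 44704740 in replicate 1. Cr2, a complement receptor of B cells, had its strongest peak at its own start site, on chromosome 1 from 195176661 to 195176860 in both libraries.

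Among T cell genes, Lck, a kinase of T cell receptor signalling, had 11 locus peaks in each library, and Cd3g and Lat had promoter peaks in both. The strongest peaks in these 3 loci lay 7940 bases or more from the gene's own start site, at other promoters. Bcl11b, a transcription factor of T cell identity, had a promoter peak in both libraries and 3 and 7 locus peaks. Cd3e had 0 locus peaks in replicate 1 and 2 in replicate 2, the stronger at its promoter on chromosome 9 from 45009577 to 45009735. Cd3d, Cd4 and Ctla4 had no promoter peak in either library, although Cd3d had 2 and 4 locus peaks and Cd4 had 2 in each.

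Among erythroid genes, Tfrc, the transferrin receptor, had its strongest peak at its own start site, on chromosome 16 from 32608741 to 32609040 in replicate 1, at rank 1017 there and 685 in replicate 2. Epor, the erythropoietin receptor, had a promoter peak in both libraries. Klf1 and Gata1, transcription factors of red cell development, had a promoter peak in replicate 2 and none in replicate 1. Klf1 had 6 and 8 locus peaks and Gata1 had 1 and 3. Alas2, which encodes the first enzyme of haem synthesis in red cells, and the globin gene Hba-a1 had no promoter peak in either library. The globin genes Hbb-bt and Hbb-bs, named after their values were seen, had promoter peaks in both.

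The macrophage and monocyte list had a promoter peak at 7 and 13 of 20 genes, at percentiles 87.8 and 99.98, and reached 98.8 and 100 with the longer lists. The dendritic cell list had 6 and 8 of 11 (43.0 and 89.1), the NK cell list 2 and 5 of 12 (30.5 and 92.5), and the plasma cell list 5 of 7 in each (93.8 and 90.1). Hmox1, the haem oxygenase of macrophages that break down red cells, had a promoter peak and 5 locus peaks in each library. Spic, a transcription factor of red pulp macrophages, had its only locus peak at its promoter in both, with signals of 0.549 and 0.523. Cd68 and Axl had a promoter peak in replicate 2 alone, and Adgre1, C1qc and Ccr2 in neither. Spi1, which encodes PU.1, had a promoter peak in both libraries and 6 and 9 locus peaks. Bst2 and Ccr9 had promoter peaks in both, and Xcr1, Clec9a and Itgax in neither. Xbp1 and Prdm1, transcription factors of plasma cells, had promoter peaks in both, and Jchain and Tnfrsf17 in neither. The perforin gene Prf1 had a promoter peak in both libraries, Nkg7 in replicate 2, and Tbx21 and Klrb1c in neither. The NK cell genes Gzma, Gzmb and Ncr1 had 0 locus peaks in both.

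The remaining 5 spleen lists lay at percentiles of 37.6 or lower in both libraries. Neutrophil genes had 0 and 1 of 12 (percentiles 14.4 and 33.98), megakaryocyte genes 1 and 2 of 10 (11.5 and 29.5), and endothelial genes 2 and 4 of 11 (6.52 and 37.6). Stromal genes had 2 and 4 of 15 (2.04 and 15.4), and stem and progenitor genes 4 and 5 of 8 (5.14 and 12.6). The neutrophil genes Ngp, Csf3r and Elane had locus peaks but no promoter peak, and Camp and Cxcr2 had neither. Itga2b, an integrin of platelets, had 2 locus peaks in each library, the strongest of them intronic, and Gp1ba and Gp1bb had no promoter peak. Pecam1, an adhesion protein of endothelium, had 9 and 12 locus peaks with a promoter peak in both, Lyve1, Cdh5 and Flt4 had no promoter peak, and Emcn had 0 locus peaks. Madcam1 and Col1a1 had promoter peaks in both, Pdgfrb and Col1a2 in neither, and Ccl19 and Ccl21a had 0 locus peaks. Tlx1, a transcription factor needed for spleen formation, had 1 locus peak in each library and no promoter peak. Myb and Meis1 had promoter peaks in both, Procr in replicate 2, and Cd34, Gata2 and Mecom in neither. Ptprc, the leukocyte antigen CD45 on chromosome 1 from 138062861 to 138175708, had 1 locus peak in replicate 1 and 8 in replicate 2, with a promoter peak in replicate 2.

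Lists of other tissues served as background. Over all of them 12.05% of genes had a promoter peak in replicate 1 and 18.1% in replicate 2, or 15.1% ± 4.26 (SD, n = 2), against 52.1% ± 12.7 (SD, n = 2) of spleen genes and 55.6% ± 2.51 (SD, n = 2) of all protein-coding genes. These pooled shares were not matched on CpG content. None of the 9 lists reached the 95th percentile in both libraries. The hepatocyte (12 genes), kidney (9), intestine (7) and adipocyte (5) lists had 0 promoter peaks, and Alb of liver and Cpa1 of pancreas had 0 locus peaks. Pancreas acinar genes had 1 and 2 of 12, neuron genes 3 and 5 of 12, muscle genes 2 and 4 of 11, keratinocyte genes 1 of 7 in each and sperm genes 3 of 8 in each. Members with promoter peaks in both libraries were Rbpjl, Syn1, Grin1, Tnni2, Actn2, Krt10, Zpbp, Dazl and Prm1. All 14 housekeeping genes and all 6 genes that escape X inactivation had promoter peaks in both libraries, at percentiles of 97.0 and 95.1, and 80.9 and 76.7. With every promoter open the escape list had its highest possible share, so it could not reach the 95th percentile. Its random lists had a median of 83.3% in both libraries.

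**Figure D1:**
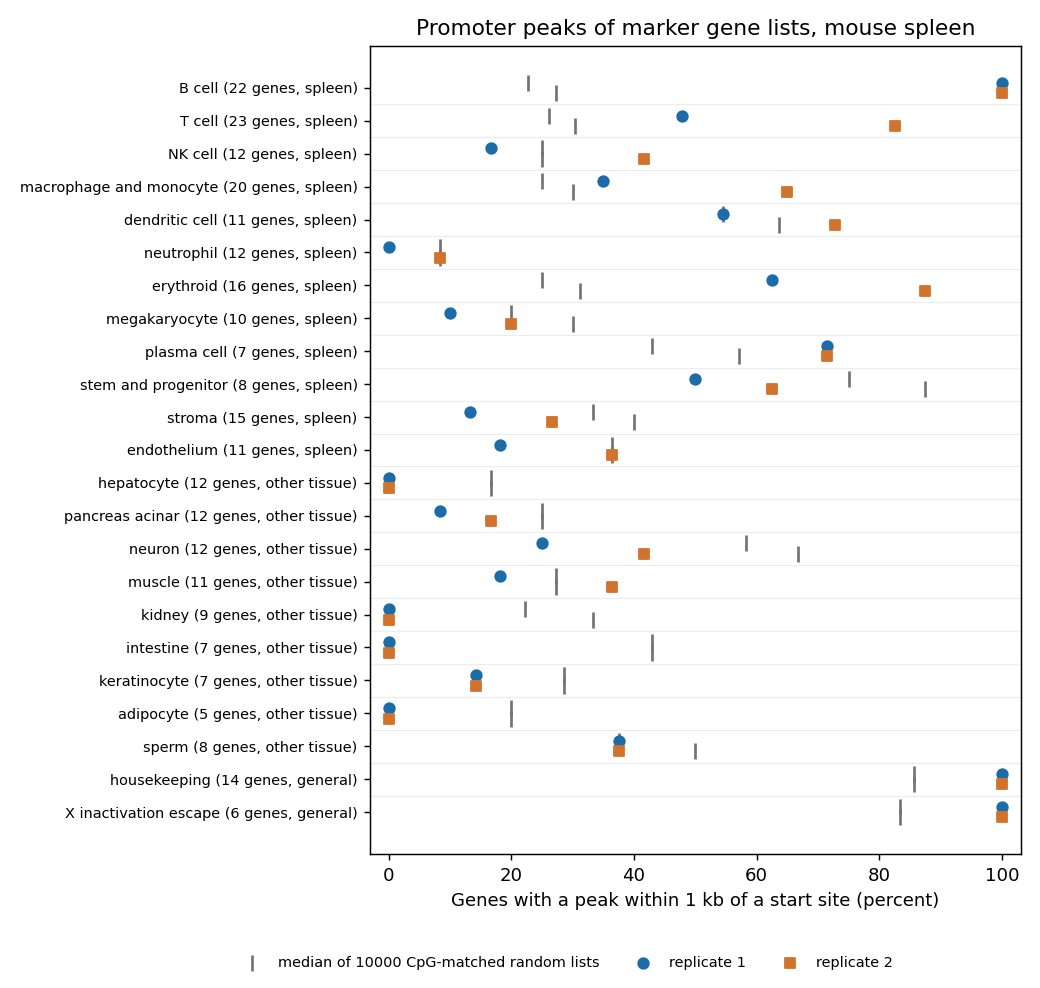
Share of the genes of each marker list with a peak within 1 kb of a start site (percent, horizontal axis), for replicate 1 (circles) and replicate 2 (squares), with the median of 10000 CpG-matched random lists as a grey bar. The B cell list is at 100% in both libraries, and the T cell list at 47.8% and 82.6%.

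A promoter peak was found in replicate 2 alone for 30 genes of the spleen lists and in replicate 1 alone for 0. The share of spleen list genes with a promoter peak was 43.1% in replicate 1 and 61.1% in replicate 2. Over all protein-coding genes it was 53.8% and 57.4%, without matching on CpG content. When replicate 2 was limited to as many peaks as replicate 1, the T cell list had 11 and 16 promoter peaks, the erythroid list 10 and 13, the macrophage and monocyte list 7 and 7, and the B cell list 22 and 22. Over all 21668 protein-coding genes 11661 and 11508 had one. The comparison at equal numbers of peaks was chosen after seeing the data.

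Peaks around the genes, promoters included, were densest for B cell genes, with a median of 1.57 ± 0.469 peaks per 10 kb (SD, n = 2) against 0.390 ± 0.0658 for all protein-coding genes. The B cell list was the 1 of 12 spleen lists at or above the 95th percentile of length-matched lists in both libraries, at 100 and 100. In replicate 2 alone the T cell (98.7), erythroid (99.4), dendritic cell (96.5) and macrophage and monocyte (96.2) lists also reached it, while in replicate 1 they lay at 44.2, 78.8, 85.3 and 30.7. Thus 5 spleen lists passed without replicate 1 and 1 without replicate 2, and 3 passed in both libraries with no flanks. The densities of the T cell list were 0.373 and 0.921, and those of the erythroid list 0.511 and 1.15.

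How far the replicates shared open regions was asked next. Of the 42454 peaks of replicate 1, 93.8% (95% Wilson interval 93.5 to 94.0) overlapped a peak of replicate 2. Of the 60683 peaks of replicate 2, 65.7% (65.3 to 66.0) overlapped one of replicate 1. Circular shifts gave at most 1.18% and 0.793%. Sharing fell with strength. Among the strongest 10% of peaks 99.9% of replicate 1 and 99.9% of replicate 2 were shared, and among the weakest 10% they were 69.9% and 17.0%. Across the 39802 shared peaks of replicate 1 the signals of the libraries had a Spearman's rho of 0.93, a description across peaks, which are not independent replicates.

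**Figure D2:**
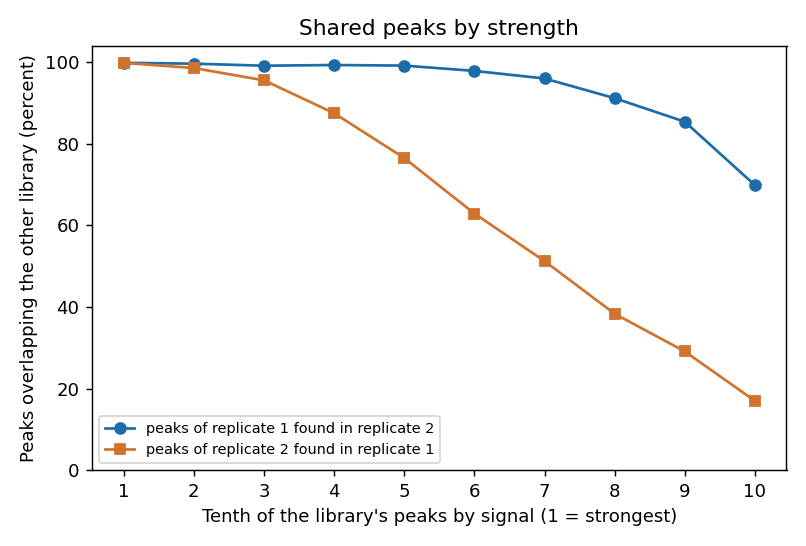
Percent of peaks overlapping the other library (vertical axis) for 10 bins of a library's peaks by signal, from the strongest at 1 to the weakest at 10 (horizontal axis), in replicate 1 (circles) and replicate 2 (squares). In bin 10, 69.9% of replicate 1 and 17.0% of replicate 2 were shared.

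The peak with the highest signal in both libraries lay on the X chromosome from 143482981 to 143483140, in intergenic sequence 35530 bases from a start site of Pak3, with signals of 66.0 and 58.1. Of the 10 strongest peaks by mean rank, those nearest to Dynlt1b, Mplkip, Esrra, Fzr1 and Dnpep lay at promoters, and the peak nearest to Cox14 in an exon 10173 bases from its start site. A pair of them lay near Gm21887 on the X chromosome, 1 at its promoter and 1 intronic, and another lay in an intron near Gm10722, on chromosome 9 from 3002041 to 3002220. Peaks in repeated sequence were not filtered here, and whether the mapping of reads raised any of these signals was not tested.

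Promoters of protein-coding genes held 40.9% of peaks in replicate 1 (Wilson 40.4 to 41.3) and 32.8% in replicate 2 (32.4 to 33.2), or 36.8% ± 5.69 (SD, n = 2). Shifted peaks lay there in at most 2.90% and 2.75%. Introns held 30.4% and 35.8% of all peaks, with lowest shifts of 40.3% and 40.5%. Intergenic sequence held 24.1% and 26.4%, with lowest shifts of 48.7% and 49.6%. The classes share 1 total, so the excess at promoters lowers the other shares by itself. Depletion of introns or intergenic sequence among peaks away from promoters is therefore not shown. Exons away from promoters held 4.59% and 5.01%, above the highest shifts of 4.11% and 4.06%. Among the strongest 10% of peaks 92.5% and 87.3% lay at promoters, and among the weakest 10% it was 26.3% and 18.9%. The promoter share was 57.1% among the strongest 21227 peaks of each library. Of CpG-rich promoters 84.1% and 87.0% had a peak, and of CpG-poor promoters 22.3% and 26.5%, over 11054 and 10614 genes.

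Footprints had a median width of 10 bases in both libraries, and 78.7% and 69.8% of them touched a peak. They were most frequent in strong peaks, with 4.91 and 4.82 per peak among the strongest 10% and 0.851 and 1.41 among the weakest 10%. Of all footprints of replicate 1, 63.7% (Wilson 63.5 to 64.0) were shared with replicate 2, and of those of replicate 2, 32.6% (32.4 to 32.7) with replicate 1. Inside shared peaks 69.8% of replicate 1 and 54.2% of replicate 2 were shared, and random placement there gave at most 37.3% and 30.6%.

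Consensus sites in footprints were counted to ask which factors' sequences lay in protected stretches. The site of CTCF, the architectural factor of chromatin loops, lay in 3422 footprints of replicate 1 against 1 with the pattern read backwards, and in 4389 against 2 in replicate 2. The ratios were 3422 (exact interval 614 to 135201) and 2194 (607 to 18126), and 201 and 129 against windows 1 kb away. The PU.1 site was found 6.35 (4.99 to 8.17) and 6.55 (5.55 to 7.77) times as often as its backward pattern, and 3.19 and 3.98 times as often as in windows 1 kb away. RUNX sites had ratios of 6.65 (5.18 to 8.65) and 10.5 (8.61 to 12.9), but 1.77 and 2.30 against windows 1 kb away. General ETS sites had 10.2 (8.15 to 12.9) and 7.29 (6.19 to 8.63), and 25.5 and 18.5 against those windows. GATA sites had ratios of 2.24 (1.61 to 3.13) and 4.85 (3.92 to 6.04), with intervals that did not overlap between the libraries. The intervals of E2A, EBF and NFY sites did not overlap either, and for NFY replicate 1 had the higher ratio. Against windows 1 kb away GATA sites were at 0.788 in replicate 1 and 1.71 in replicate 2.

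Of 22 consensus sequences with a backward control, 18 were more frequent forward than backward in footprints of both libraries. NFY sites had ratios of 10.8 (8.85 to 13.2) and 7.64 (6.63 to 8.84), EBF sites 2.25 (1.81 to 2.79) and 3.29 (2.81 to 3.86), IRF sites 8 (3.16 to 26.0) and 7.14 (4.06 to 13.5), and MEF2 sites 8.80 (3.50 to 28.4) and 8.31 (4.66 to 16.1). Against windows 1 kb away NFY sites were at 5.57 and 4.12, EBF sites at 4.96 and 6.49, IRF sites at 3.33 and 4, and MEF2 sites at 1.33 and 1.77. E2A sites had ratios of 15.2 and 26.4 and octamer sites 46.6 and 59.5, but their backward patterns hold a rare CpG, and against windows 1 kb away they were at 1.28 and 1.56, and 1.88 and 2.03. Sites of NRF1 were at least 127-fold more frequent than backward in replicate 1 and 417 (74.4 to 16510) times in replicate 2, and those of YY1 at least 38.3-fold and 171 (30.3 to 6793) times. The backward patterns of both hold more CpGs than the forward ones. Against windows 1 kb away NRF1 sites were at 127 and 52.1, and YY1 sites at 38.3 and 34.2. ZNF143 sites were at least 21-fold and 29.3-fold more frequent, and REST sites at least 3.67-fold and 8-fold. C/EBP sites had ratios of 2.10 (0.946 to 4.99) and 2.89 (1.66 to 5.25), or 5.25 and 4.73 against windows 1 kb away, and AP-1 sites 1.53 (1.25 to 1.88) and 2.09 (1.82 to 2.40), or 0.914 and 1.24 against windows 1 kb away. NF-kB sites were below their backward pattern, at 0.576 (0.513 to 0.645) and 0.619 (0.572 to 0.671), but at 2.21 and 2.35 against windows 1 kb away. T-box sites were at 0.544 (0.366 to 0.799) and 0.694 (0.540 to 0.889) and TCF7/LEF1 sites at 0.593 (0.411 to 0.848) and 1 (0.794 to 1.26), and against windows 1 kb away they were at 0.406 and 0.561, and 0.481 and 0.793. HNF4 sites, of a nuclear receptor of liver and gut, were at 2.71 (1.09 to 7.64) and 2.71 (1.44 to 5.42) and at 0.731 and 0.760 against windows 1 kb away, and HNF1 sites were in 0 footprints. The SP/KLF box was 26.4 and 16.8 times as frequent as in windows 1 kb away.

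**Figure D3:**
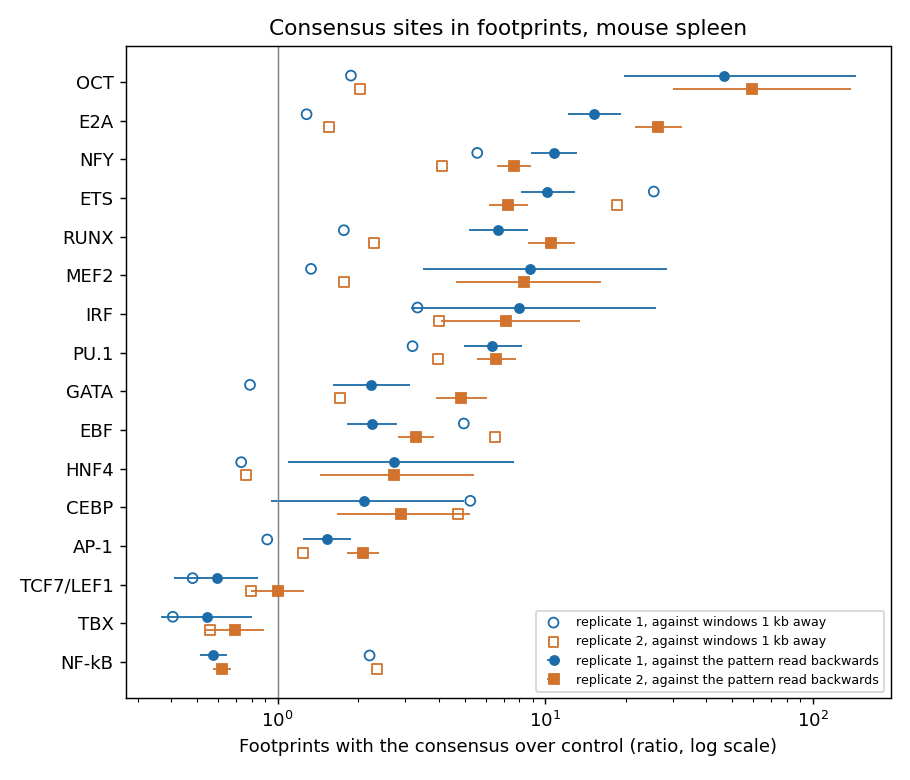
Footprints holding a consensus site over those holding the control (ratio, log axis) for replicate 1 (circles) and replicate 2 (squares); filled symbols are against the pattern read backwards with 95% exact intervals as bars, open symbols against windows 1 kb away. PU.1 stands at 6.35 and 6.55 and NF-kB at 0.576 and 0.619 against the backward pattern.

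Sites were also counted apart in distal and promoter peak centres. In peak centres away from promoters PU.1 sites had ratios of 8.90 (7.41 to 10.8) and 9.65 (8.41 to 11.1), against 3.01 (2.35 to 3.89) and 3.82 (3.03 to 4.85) at promoters. RUNX sites had 6.50 (5.33 to 7.98) and 7.43 (6.37 to 8.71) in distal centres and 2.02 (1.40 to 2.96) and 2.06 (1.52 to 2.83) at promoters. ETS sites had 1.45 (1.14 to 1.86) and 1.33 (1.10 to 1.61) in distal centres and 14.2 (10.6 to 19.5) and 11.5 (8.89 to 15.2) at promoters, but the forward ETS pattern holds a CpG that its control lacks, and CpG content was not separated from the sites here. NFY sites had 2.87 (2.39 to 3.47) and 2.28 (1.98 to 2.63) against 13.6 (11.1 to 16.9) and 12.9 (10.6 to 15.8). CTCF sites lay in 3317 and 3436 distal centres and in 189 and 188 promoter centres.

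The X chromosome carried 6.02 peaks per Mb in replicate 1 and 8.36 in replicate 2, which was 0.351 and 0.341 of the mean autosome, or 0.346 ± 0.00718 (SD, n = 2). The autosomes ranged from 11.1 and 16.6 on chromosome 14 to 28.8 and 39.97 on chromosome 11. Per protein-coding gene X had 1.08 and 1.51 peaks, and the lowest autosome 1.42 and 1.99. The Y chromosome carried 8 and 13 peaks in these libraries of females.

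**Figure D4:**
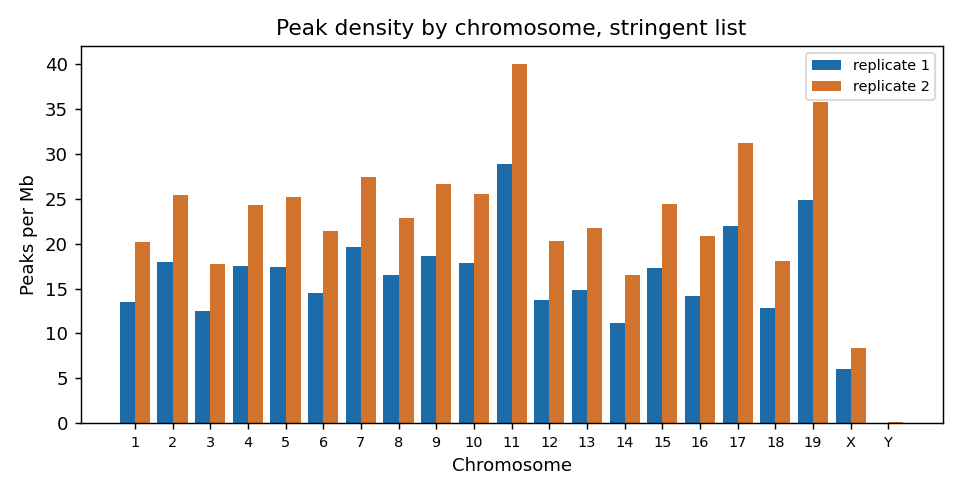
Peaks per Mb (vertical axis, from 0) on each chromosome (horizontal axis) in replicate 1 and replicate 2. The X chromosome stands at 6.02 and 8.36, below all 19 autosomes in both libraries.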

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

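The comparison of locus peaks at equal peak strength was chosen only after the counts per gene list had been seen; the other tests here were fixed before the value they measure was seen.

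The cut rate track, which the comparisons of the report do not use, listed bases with an FDR under 0.05 outside every deposited peak, even of the longer list. They made up 42.9% of the listed bases in replicate 1 (8.69 Mb) and 40.7% in replicate 2 (11.3 Mb). No control sample was analysed here to set them against.

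Replicate 1 had fewer peaks and footprints than replicate 2, for which sequencing depth is a candidate explanation: 98.6% of the strongest 21227 peaks of replicate 2 lay in the longer list of replicate 1, so strong peaks were rarely missing. A difference in cell type makeup between the samples also stays open: in 3 of 12 spleen lists (T cell 50.4%, dendritic cell 48.7% and megakaryocyte 50%) the share of replicate 2 peaks without a partner in replicate 1 lay over 10 points from the 32.2% of all genes, with an exact interval excluding it, but against the longer list of replicate 1 only the T cell list met both conditions (30.4%, exact interval 22.2 to 39.7, against 17.4%). At equal peak strength 3 of the 9 lists with at least 20 locus peaks met both conditions against the expected share, B cell at 35.4% (29.4 to 41.7) against 24.7%, T cell at 50.4% (41.0 to 59.9) against 35.5% and dendritic cell at 48.7% (37.0 to 60.4) against 33.5%, and all 9 lay above expectation. Of the smaller spleen lists, NK cell and neutrophil also lay above, and stem and progenitor, with 18 peaks, below, at 33.3% against 44.9%. The neuron list, of another tissue, was above too, at 43.2% (27.1 to 60.5) against 37.6%, an interval that includes the expected share. Of the smaller lists of other tissues, pancreas acinar, muscle and sperm lay above expectation. Hepatocyte, kidney, intestine, keratinocyte and adipocyte lay below it. Whether the excess was particular to spleen lists was thus not settled. Against the longer list the T cell list was at 30.4% against 18.96%, the B cell list at 19.9% (15.1 to 25.5) against 12.4% and the dendritic cell list at 21.1% (12.5 to 31.9) against 17.4%, while housekeeping genes, at 15.3% against 15.3% in the shorter list, were at 12.5% (5.88 to 22.4) against 6.75%. Of the 9 lists, plasma cell alone lay below expectation against the longer list, at 14.7% against 16.3%. Peaks of one gene are not independent, so these intervals are too narrow, the explanations can act together, and with 1 group no factor of the design bears on either.

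Peaks were called on the Y chromosome although the labels give females. The tables argue against a male sample or male cells, since 0 of 4 promoters of single-copy Y genes named for this test (Ddx3y, Kdm5d, Eif2s3y and Uty) had a peak in either list of either library. Reads from matching sequence elsewhere are a candidate source: 18 of 21 Y peaks (85.7%) matched another chromosome at 95% identity or more over at least 90% of their length. These were 7 of 8 in replicate 1 and 11 of 13 in replicate 2, and regions called in both libraries count in each. Of the rest, 1 region called in both libraries matched X at 93.4% and 92.9% identity, and 1 peak of replicate 2 had no match.

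The X chromosome had 0.346 of the peak density of the mean autosome. Fewer genes per Mb are not the whole cause, since X had 1.30 peaks per protein-coding gene (mean of both libraries), below the lowest autosome in each. Promoters on X that are open less often remain a candidate explanation: 77.2% of CpG-rich X promoters had a peak (75.1% and 79.3%), below the lowest autosomes at 77.9% and 81.1%. That gap is small beside the difference in density, so it leaves most of the pattern open. The sex of the animals, the mapping of reads on X and the hybrid genome were not tested.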

How the results depend on the processing

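Equal numbers of peaks, and leaving out a replicate for the numbers of peaks and footprints, were chosen after seeing the data; the other alternatives were fixed before. Of the values that answer a comparison, 50 stayed within their limit, 24 moved and 0 reversed; of those of single lists, genes and motifs, 709 stayed, 182 moved and 7 reversed. Alternatives in which the control of a motif was 0 gave no ratio. Leaving out 1 of 2 libraries leaves the other's value, with no test. The cause was not tested unless the alternative itself gives it. The mean for peaks called per library fell to 23392 above the median signal of the smaller list, by construction. For peaks shared between replicates, replicate 1 in 2 gave 84.7% with reciprocal overlap, 87.3% among the strongest 21227 and 89.95% in the longer lists, and peaks shared between replicates, replicate 2 in 1, gave 59.2%, 87.4% and 61.7%. The agreement of peak strength between replicates was a rho of 0.848 away from promoters and 0.933 with reciprocal overlap. The share of peaks at promoters was 42.5% with windows of 2500 bases and 57.1% among the strongest 21227. By promoter peak share of cell type lists, 1 spleen list reached the 95th percentile with the strongest 21227 peaks, 1 with random lists without matching, 4 with the longer list, and 3 to 4 with a replicate left out. By locus peak density of cell type lists, 3 did with no flanks and 1 to 5 with a replicate left out. The footprints shared between replicates were 69.4% of replicate 1 and 35.7% of replicate 2 with overlap of 1 base, 47.4% and 25.7% with reciprocal overlap, and 69.8% and 54.2% inside shared peaks (footprints shared between replicates, replicate 2 in 1). In peak density by chromosome the ratio of X to autosomes was 0.299 for the strongest 21227 peaks, 0.520 per protein-coding gene and 0.312 with equal numbers of peaks. Against windows 1 kb away NF-kB, ratio in footprints, rose above 1 to 2.28, as did NF-kB, ratio in peak centres, to 2.27. HNF4, ratio in footprints, fell below 1 to 0.745, HNF4, ratio in peak centres, to 0.722 and MEF2, ratio in peak centres, to 0.971. In peak centres HNF4 was also at 0.989 in distal peaks and ranged from 0.927 to 1.09 with a replicate left out. Of 90 named genes, 2 had a promoter peak in fewer libraries with windows of 500 bases, 9 in more with 2500 bases, 18 in more with the longer list, 20 in fewer with the strongest 21227 peaks and 6 in fewer with equal numbers. Sharing was lowest for weak peaks, with 17.0% of the weakest 10% of replicate 2 found in replicate 1, so a promoter peak missing from replicate 1 is not shown to be absent there. Whether depth limits these peaks was not settled, since total depth is unknown.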

Other observations

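The shares, windows and genes given here were chosen after the peaks and footprints had been seen, and no test was run on them.

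Consensus sites inside peaks differed in how often a footprint covered their midpoint base, which is what covered means here. Footprints were most frequent in strong peaks, and sites were not matched on the strength of their peaks or on lying at promoters. Differences between factors are thus not shown at equal peak strength. CTCF sites were covered in 86.9% of cases in replicate 1 and 97.1% in replicate 2, and NRF1 sites in 96.4% and 97.4%. Sites of REST, a repressor of neuronal genes, were few and were covered in 64.0% (16 of 25) and 94.7% (18 of 19). ETS sites were covered in 48.3% and 60.6% (13.0% and 17.2% for the pattern read backwards), EBF sites in 48.5% and 67.5% (34.7% and 41.3%), and SP/KLF boxes in 69.0% and 77.4%. PU.1 sites were covered in 12.3% and 16.8% (backward pattern 8.53% and 10.7%), RUNX sites in 17.7% and 28.5% (12.1% and 9.29%), and GATA sites in 15.9% and 29.5% (10% and 11.1%). Sites of 4 factors were covered less often than their backward pattern in both libraries. Forward and backward sites were not matched on the strength or place of their peaks either, and the backward E2A pattern holds a CpG that the forward one lacks. The values therefore do not show that these factors' sites were less protected. NF-kB sites were at 19.4% against 36.3% in replicate 1 and 23.7% against 46.4% in replicate 2, E2A sites at 15.1% against 24.4% and 16.8% against 22.8%, T-box sites at 8.24% against 17.0% and 11.8% against 18.5%, and AP-1 sites at 8.48% against 13.7% and 12.6% against 13.1%.

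The immunoglobulin heavy chain region on chromosome 12 from 113400001 to 113500000, which holds Ighm, Ighd and the joining and diversity segments, had 4 peaks in replicate 1 and 49 in replicate 2, and 6 and 55 in the longer lists. Their median signals were 0.781 and 0.405, below the medians of all peaks, 1.39 and 1.14. Ranked by a binomial probability against the 58.8% of all peaks that replicate 2 held, it was the most uneven of 12573 windows of 100 kb. That ranking takes no account of peak strength. The weakest 10% of replicate 2 peaks had a median signal of 0.425, and 17.0% of them were found in replicate 1. The low count in replicate 1 therefore does not show closed chromatin in the immunoglobulin region. The window on chromosome 2 from 167200001 to 167300000, with Ptgis and B4galt5, had 4 and 41 peaks, of median signal 1.01 and 0.169. The window on chromosome 9 from 97300001 to 97400000, with Trim42, had 0 and 17, of median signal 0.0974 in replicate 2, and that on chromosome 6 from 99300001 to 99400000, with Foxp1, had 1 and 18, of median signal 2.60 and 0.938. The lowest signal of any peak in the shorter list was 0.1055 in replicate 1 and 0.0564 in replicate 2. The median of the Trim42 window lay below that of replicate 1, so the count of 0 does not show closed chromatin there.

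The densest window by mean count lay on chromosome 11 from 69000001 to 69100000, with Aurkb, Per1 and Vamp2 among its 7 coding genes, and had 29 and 38 peaks. A histone gene cluster on chromosome 13 from 23500001 to 23600000 with 15 coding genes had 27 and 33 peaks. The window on chromosome 4 from 3000001 to 3100000 holds 0 coding genes and had 30 and 26. No filter for repeated sequence was applied here, and whether the mapping of reads raised this count was not tested. The window on chromosome 17 from 34100001 to 34200000, with the antigen presentation genes H2-DMa, Tap1, Psmb8 and Psmb9, had 22 and 31.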
